A study of Mus musculus with 16 samples.

How the data were processed

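Gene expression was measured in 16 Affymetrix arrays of 8 immortalised mouse haematopoietic progenitor lines, each with 1 untreated array and 1 array after 48 h with 2 µg/ml doxycycline. Per the labels, 6 lines carried a fusion oncogene that doxycycline switches off through the tetracycline transactivator: MA1, MA3 and MA4 with MLL-AF9, and ME4, ME5 and ME7 with MLL-ENL. The other 2 lines, cMA3 with MLL-AF9 and cME3 with MLL-ENL, expressed the fusion constitutively and served as controls for the system. The lines are described as independent, so the line was the replicate. No array was repeated, and the spread within a line was not measured.

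The deposited values are signal intensities per probe set. Per the submitters' processing notes they were made with MAS5, whose version is not given in the sources used here. The values are linear, and the authors' scaling shows in the trimmed mean signal, which was between 174.8 and 178 on the 16 arrays. The median intensity was between 42.9 and 51.2, and between 40.5% and 44.7% of the probe sets of an array lay under a signal of 32. The table used here holds 28922 probe sets with signal values only. Of these, 40 are array controls and were left out. A probe annotation supplied with the table gave 1 gene symbol for 23491 probe sets, several for 658 and none for 4733. Symbols were looked up by gene ID in a RefSeq gene table of assembly GRCm38.p6 for 23409 probe sets, and 0 symbols changed. Gene positions in that table were used only to find the genes nearest to Mycn.

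Values were transformed to log2(signal + 16). A fold change on this scale understates the change of weakly expressed genes. The probe set with the highest mean over the 16 arrays stood for its gene, giving 12850 genes, and 5971 genes had more than 1 probe set. Genes whose mean lay above the 33rd percentile of all probe sets, a signal of about 19.2, were tested, which left 9420. In 28 cases a value was listed at 0. For the genes named in the text, no other probe set of the gene was called in the opposite direction. In at least 1 comparison the gene passed and another of its probe sets did not for Ash2l, Bcl2l11, Bid, Bmi1, Chic2, Fen1, Hoxa5, Ighm, Kit, Macir, Pbx3, Pdk1 and Slc2a3. Another probe set passed where the chosen one did not for Cdkn1a in the conditional and the MLL-ENL lines, for Kit, Kmt2a and Mef2c in the MLL-AF9 lines, and for Slc2a3 between untreated lines. For Hpgd, Ighm, Myc, Myb, Hoxa10, Slc2a3, Srm, Fkbp11 and Ssbp2, among others, the name of the chosen probe set marks it as one that may match several transcripts. The number of arrays limits the precision.

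The doxycycline comparisons came from 1 limma model (lmFit and eBayes with an intensity trend, limma 3.58.1 in R 4.3.3) of all 16 arrays, with the cell line as replicate block and separate doxycycline effects for the conditional MLL-AF9 lines, the conditional MLL-ENL lines and the constitutive lines. The fit had 5 residual degrees of freedom and about 10.3 after moderation. Each SE of a doxycycline effect uses 1 spread per gene, pooled over all lines. It does not show how far the lines of a single comparison lay apart. The effect in the conditional lines was the mean of the effects for MLL-AF9 and MLL-ENL. Untreated conditional lines were compared between oncogenes in a limma fit of 6 arrays without a block. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Each adjusted p in the text is from these limma fits, for gene lists from camera, and for array measures from exact sign-flip tests. Where it is given among all probe sets, it is from the same limma model fitted to all probe sets above the filter. The pairing of arrays comes from the cell line. The deviations of the untreated and treated array of a line from their group means correlated across genes at 0.461 in MA1, 0.6 in MA3, 0.178 in MA4, 0.619 in ME4, 0.472 in ME5 and 0.552 in ME7.

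In all, 35 gene lists were fixed before the data were examined, and the 26 with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01. No call of any list in any comparison held when the correlation was estimated. The directional and mixed tests of fry were run as alternatives. The genes named were also fixed by rule before the data were examined: up to 8 per direction with the largest change among those that passed and moved the same way in every line (5 for comparisons between oncogenes, and the 3 with the smallest p where none passed), 31 preset genes, and up to 4 members with the smallest p of each list described. Of the preset genes 27 were tested, 2 (Cd34 and Mllt3) lay below the filter and 2 (Flt3 and Cebpe) were not analysed here.

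Alternatives covered the pseudocount (1 and 64), a floor of 32, quantile normalization, median centring, no filter and a filter at the 60th percentile, eBayes without trend and with robust estimation, the mean of the probe sets of a gene, all probe sets, a minimum of 2-fold, the model without the line block, smaller sets of arrays, and leaving out each line. The fit of the conditional effect without MA3 and MA4 was chosen after seeing the data. Other splits of the lines were refitted, and the split of the conditional against the constitutive lines used 1 common doxycycline effect for all lines treated as conditional, because other choices of 2 lines leave unequal numbers per oncogene.

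The fit was tested on simulated arrays of the 9420 genes with the means and spread of the real arrays. Changes of 0.5, 1 and 2 were planted in 67, 67 and 66 genes, alike in every conditional line. The noise was independent between genes, and no other gene changed. In the real arrays changes were far more common and uneven over the lines. The shares and false calls below therefore describe the simulated setting only. For the effect in the conditional lines it recovered 82.1% of the genes changed by 0.5 on the log2 scale, 100% of those changed by 1 and 100% of those changed by 2, with 9 false calls. For the conditional minus constitutive comparison it recovered 2.99%, 79.1% and 98.5%, with 10 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.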

Results

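RNA of 8 mouse haematopoietic progenitor lines was hybridised to 16 arrays to follow what happens to gene expression when the fusion oncogene that immortalised the cells is switched off. The lines had been made by retroviral transduction of lineage-negative bone marrow cells and grew in stem cell factor, IL-3 and IL-6. In the 6 conditional lines, 3 with MLL-AF9 and 3 with MLL-ENL, 48 h of doxycycline at 2 µg/ml turns the fusion gene off. In the 2 constitutive lines, 1 per oncogene, it does not, so they serve as the control for doxycycline itself. With 1 pair of arrays per line, an effect of doxycycline there cannot be told apart from a difference between the 2 cultures of a line. Each line gave 1 untreated and 1 treated array. Both probe sets of Kmt2a, the mouse MLL gene, were higher with doxycycline in the 6 conditional lines, by 0.37 and 0.36 on the log2 scale (adjusted p = 0.0178 and 0.00671 among all probe sets). Without MA4 or ME5 the chosen Kmt2a probe set did not pass (adjusted p = 0.0587 and 0.0705). Mllt1, the mouse ENL gene, was lower, with a change of -0.25 (adjusted p = 0.0348 among all probe sets), and Mllt3, the AF9 gene, lay below the filter. The labels do not say which part or species of sequence the fusion genes hold, so these probe sets check nothing about the loss of the fusion transcript.

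Switching off the fusion gene in the 6 conditional lines was accompanied by a rise of neutrophil granule and maturation genes and a fall of Hoxa genes, Meis1, Myc and the ribosome biogenesis genes. Ltf, which encodes the secondary granule protein lactotransferrin, rose by 5.45 ± 0.27 on the log2 scale (SE, n = 6 lines, adjusted p = 5.45e-07), from a mean signal of 143 to 5227. Ifitm6 rose by 5.21 ± 0.29, Ceacam10 by 5.18 ± 0.20, Itgb2l by 4.57 ± 0.14, the neutrophil surface protein gene Cd177 by 4.27 ± 0.21, and Mapk13, Chil1 and the glucose transporter gene Slc2a3 by 3.78, 3.78 and 3.68. All 24 tested genes of the neutrophil list rose, with a median of 2.37. Adjusted over the list alone 24 rose, and in the lists below this count is given where it differs from that over all genes. The list passed with camera (adjusted p = 1.91e-12, but adjusted p = 0.337 with an estimated correlation). Camp, encoding the granule peptide cathelicidin, rose by 3.26 ± 0.31, and Pglyrp1 and Fcnb by 3.54 and 3.49. S100a9 and S100a8, which encode abundant neutrophil cytosolic proteins, rose by 1.29 ± 0.14 and 0.74 ± 0.09. The integrin gene Itgam rose by 2.27 ± 0.14. Each of these genes rose in 6 of 6 lines.

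**Figure D1:**
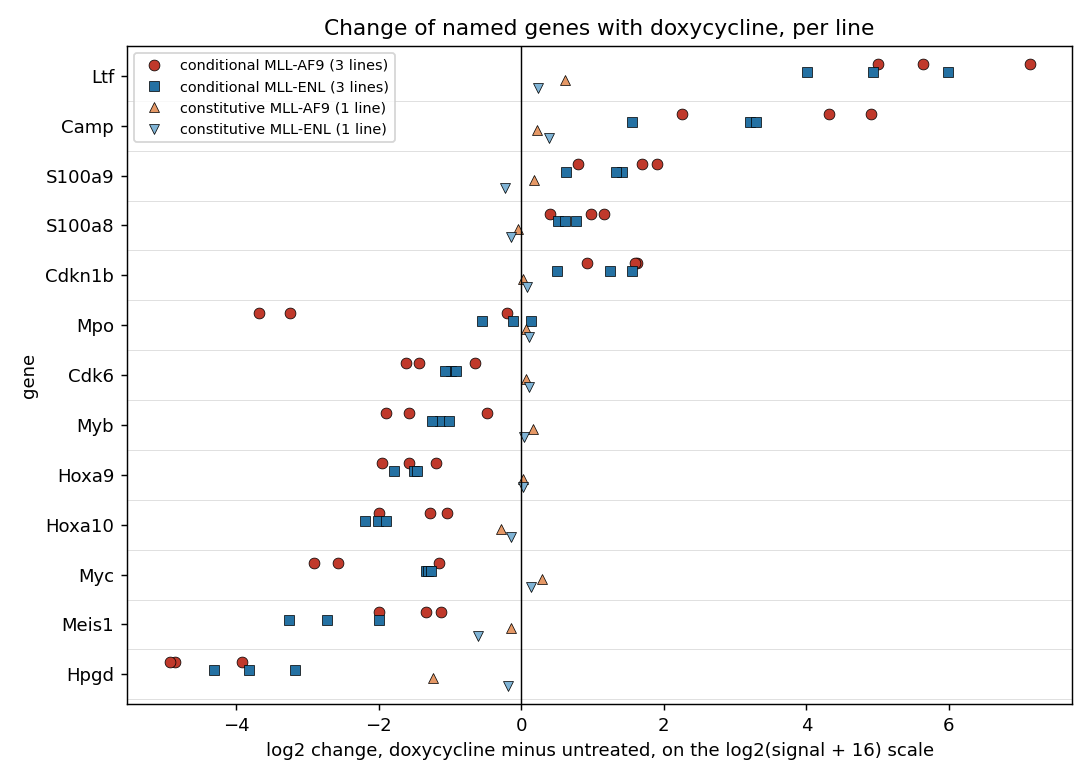
Log2 change with doxycycline of 13 named genes in each of the 8 lines, on the log2(signal + 16) scale, with 1 symbol per line and colour and shape giving the oncogene and the kind of line. Ltf and Camp lie far to the right and Meis1, Hoxa9 and Hpgd to the left in the conditional lines, while the constitutive lines lie nearer to 0.

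Among the genes that MLL fusions are known to sustain, Hoxa9 changed by -1.58 ± 0.09 (adjusted p = 1.32e-06), Hoxa10 by -1.74 ± 0.11, Hoxa11 by -1.84 ± 0.14, Hoxa5 by -1.22 ± 0.12, Hoxa7 by -1.15 ± 0.12 and the cofactor gene Meis1 by -2.07 ± 0.17, each lower in 6 of 6 lines. In the list of the HOXA cluster and its cofactors 8 of 10 tested genes fell and 1 rose (9 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.00234, adjusted p = 0.337 with an estimated correlation). Pbx3 was at -0.20 ± 0.09 and did not pass (adjusted p = 0.0713), although it did without ME7 (adjusted p = 0.0421). Of 19 other reported fusion targets, 11 fell and 4 rose (camera adjusted p = 0.0382, adjusted p = 0.337 with an estimated correlation). The changes that passed included Myb at -1.22 ± 0.15, Cdk6 at -1.11 ± 0.11, Six4 at -1.42, Sox4 at -1.51, Tcf4 at -1.16 and Mef2c at -0.51, whereas Id2, an inhibitor of helix-loop-helix factors, rose by 2.37 ± 0.16. Bcl2 and Jmjd1c were at -0.30 ± 0.16 and 0.14 ± 0.11 and did not pass (adjusted p = 0.118 and 0.281), but Bcl2 passed without MA3 (adjusted p = 0.00848) and Jmjd1c without MA1 (adjusted p = 0.031). The genes with the largest falls were Hpgd, which encodes a prostaglandin-degrading enzyme (-4.17 ± 0.18), the glycine receptor subunit gene Glra3 (-3.21 ± 0.16), Aldh1a7 (-2.66 ± 0.62, uneven over the lines), the chemokine gene Ccl9 (-2.60 ± 0.36, but -0.26 in MA3), the spermidine synthase gene Srm (-2.58 ± 0.23), Fkbp11 (-2.57 ± 0.24), BC035044 (-2.45 ± 0.32) and Frat2 (-2.37 ± 0.16).

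Genes for making ribosomes fell together. All 37 tested genes of the MYC-regulated ribosome biogenesis list fell, with a median of -1.41 (camera adjusted p = 3.28e-14, adjusted p = 0.583 with an estimated correlation), among them Noc3l at -1.35, Utp20 at -1.61 and Ddx21 at -1.39. Myc itself fell by 1.76 ± 0.18. The values were uneven over the lines: the median of the list was -2.01 in MA3 and -2.31 in MA4 and between -1.21 and -0.997 in the other 4, and Myc was at -2.57 and -2.90 in these 2 lines and between -1.34 and -1.15 in the others. Of the mitochondrial ribosome list 41 of 42 fell, with a median of -0.69 (camera adjusted p = 1.91e-12, adjusted p = 0.583 with an estimated correlation), such as Mrpl12 at -1.62 and Mrps18b at -1.55, and with line medians of -0.91 in MA3, -0.99 in MA4 and between -0.63 and -0.42 in the others. Of the oxidative phosphorylation genes 25 of 45 fell and 1 rose (23 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.000461, adjusted p = 0.586 with an estimated correlation). The genes of the cytosolic ribosomal proteins had a median of 0.01 as given, -0.07 after quantile normalization and -0.03 after median centring, with a mean of -0.04, and 2 of 27 fell (1 adjusted over the list alone, camera adjusted p = 0.739). Of 24 glycolysis and hypoxia genes 14 fell and 4 rose (camera adjusted p = 0.0218, adjusted p = 0.586 with an estimated correlation), among them Pdk1 at -1.96. The median of this list was -0.39 in the conditional lines and -0.27 in the constitutive lines, and the list did not pass for the difference between them (camera adjusted p = 0.781).

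Cell cycle genes did not move as a block. Of the 17 tested CDK inhibitors and cell cycle exit genes 12 rose and 0 fell, with a median of 0.95 (camera adjusted p = 0.000461, adjusted p = 0.337 with an estimated correlation). Mxd1, a MYC antagonist, rose by 2.75 ± 0.21, Ccng2 by 1.73 ± 0.10, Cdkn2d by 1.38 ± 0.08 and Cdkn1b by 1.24 ± 0.14, while Cdkn1a was at -0.09 ± 0.10 with its chosen probe set (adjusted p = 0.469) and at -0.32 ± 0.10 with its other one, which passed (adjusted p = 0.0201 among all probe sets). Of 31 mitosis genes 20 rose and 1 fell (camera adjusted p = 0.00108, adjusted p = 0.586 with an estimated correlation), including Nusap1 at 0.96 and Kif23 at 1.03, with a list median of -0.003 in MA3, 0.12 in MA4 and between 0.37 and 0.48 in the others. Of 36 genes of G1/S and DNA replication 14 fell and 3 rose (12 fell and 2 rose adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0794). E2f2 and Cdc25a rose by 2.03 and 1.29, and Ung and Fen1 changed by -1.43 and -1.19. The median of this list was -0.86 in MA3 and -0.58 in MA4, and between 0.01 and 0.09 in the other 4 conditional lines.

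Among the lists of other myeloid cells that of monocytes passed. Of 24 monocyte and macrophage genes 17 rose and 2 fell, with a median of 0.68 (camera adjusted p = 0.000516, adjusted p = 0.562 with an estimated correlation), for example Ctss at 1.79 and Mpeg1 at 1.69. Csf1r and Cd14 were at 0.46 ± 0.22 and 0.20 ± 0.22 and did not pass (adjusted p = 0.0967 and 0.424), and Irf8 was at -0.08. Without MA1 both Csf1r and Cd14 passed (adjusted p = 0.00542 and 0.0372), and without ME7 Csf1r did (adjusted p = 0.0481). The 7 mast cell and basophil genes included 3 that rose, such as Alox5 at 2.03, and 2 that fell, such as Mcpt8 at -1.06 (camera adjusted p = 0.598). Of 15 MYB-regulated and early myeloid genes 7 fell and 2 rose (camera adjusted p = 0.1). Mpo, the myeloperoxidase gene, fell by 1.27 ± 0.35, but its change was -3.24 in MA3 and -3.68 in MA4 and between -0.55 and 0.14 in the other 4 lines. Elane was at -0.27 ± 0.14 (adjusted p = 0.114; 9.5e-05 without MA1). Of 11 stem and progenitor markers 5 fell, including Kit and Gata2 at -0.36 and -0.94, and 4 rose, with a median of 0.05 and a mean of -0.10 (camera adjusted p = 0.642). In the list of NF-kB and inflammatory cytokine genes 11 of 16 rose and 2 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.0218, adjusted p = 0.61 with an estimated correlation), among them Nfkbia at 1.65. Of 21 interferon response genes 15 rose and 2 fell (16 and 2 adjusted over the list alone, camera adjusted p = 0.00576, adjusted p = 0.586 with an estimated correlation), and of 27 cytokine receptor and signalling genes 14 rose and 5 fell (16 and 5 adjusted over the list alone, camera adjusted p = 0.0473, adjusted p = 0.586 with an estimated correlation), including Csf3r, the G-CSF receptor gene, at 1.76. Without MA3, ME4 or ME5 the cytokine receptor list did not pass (adjusted p = 0.0699, 0.0513 and 0.0587). Some lists share members: Csf3r is also on the neutrophil list, and Itgam is on both the monocyte and the integrin list. Calls of different lists are therefore not independent of each other.

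**Figure D2:**
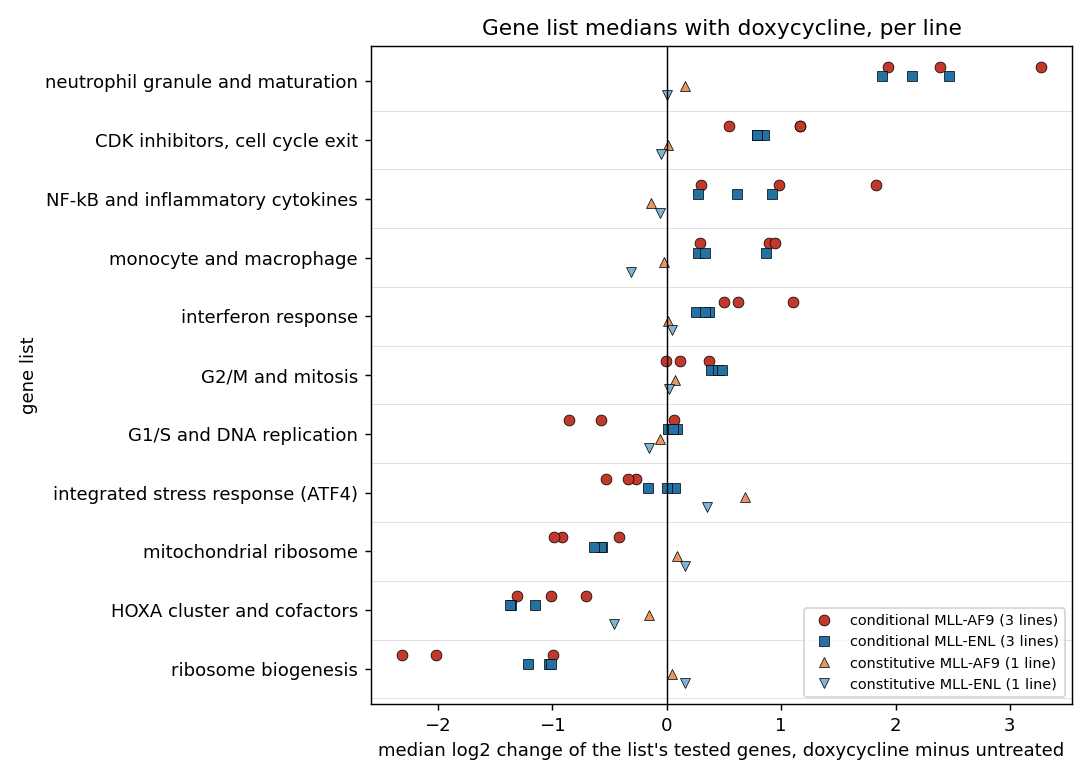
Median log2 change with doxycycline of the tested genes of 11 gene lists, with 1 symbol per line. The neutrophil medians lie between 1.88 and 3.27 in the 6 conditional lines and at 0.16 and 0.00 in the constitutive lines, and the ribosome biogenesis medians between -2.31 and -0.997 against 0.05 and 0.16.

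In total 6026 of 9420 tested genes (64%) passed in the conditional lines, 3084 higher and 2942 lower, and 1028 of them changed at least 2-fold. A list with about this share of calls passed no more often than the tested genes at large. The median signal of the array was higher with doxycycline in 6 of 6 conditional lines, with a change of 3.22 ± 1.9 (SD), against -2.5 and -2.9 in cMA3 and cME3. The percentage of probe sets under a signal of 32 was lower in 6 of 6, with a change of -1.62 ± 0.842, against 1.8 and 1.2, and the share of the total signal in the 100 strongest probe sets was higher in 6 of 6, by 0.767 ± 0.509 percentage points, against 0.1 and 0.8. For each of these 3 an exact two-sided sign-flip test gave p = 0.0312, the smallest it can give (adjusted p = 0.052 over 5 measures). The log2 ratios of 3' to 5' signal had mean changes of -0.0696 for actin and -0.0413 for Gapdh, higher in 2 and in 1 of 6 lines (exact p = 0.125 and 0.0625). The SD of the log2 changes across genes was 0.835 in MA3 and 0.976 in MA4 and between 0.575 and 0.678 in the other 4 conditional lines.

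The effect was also fitted for each oncogene. In the MLL-AF9 lines 5258 genes passed, 2707 higher and 2551 lower, and in the MLL-ENL lines 4106, 2018 higher and 2088 lower. Ltf rose by 5.93 ± 0.39 and 4.98 ± 0.39, Meis1 changed by -1.48 ± 0.24 and -2.66 ± 0.24, Myc by -2.21 ± 0.25 and -1.30 ± 0.25, and Hoxa9 by -1.58 ± 0.13 and -1.58 ± 0.13, in the MLL-AF9 and MLL-ENL lines. In MA1, an MLL-AF9 line, Myc was at -1.15, where the MLL-ENL lines lay between -1.34 and -1.27, and Meis1 at -2.00, which was also its value in ME5. Hpgd changed by -4.57 and -3.77, and Glra3 by -3.08 and -3.34. The fold changes of the 2 oncogenes correlated across genes at a Pearson r of 0.889 and a Spearman rho of 0.861, where genes are not independent replicates. The calls shared 1717 genes that rose, where independent lists would share 580, and 1718 that fell, where independent lists would share 565, and 8 genes passed in opposite directions. Both sets of calls use the same spread per gene from 1 fit, so independent lists are too low a yardstick. Without ME7 the MLL-ENL count was 2424.

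**Figure D3:**
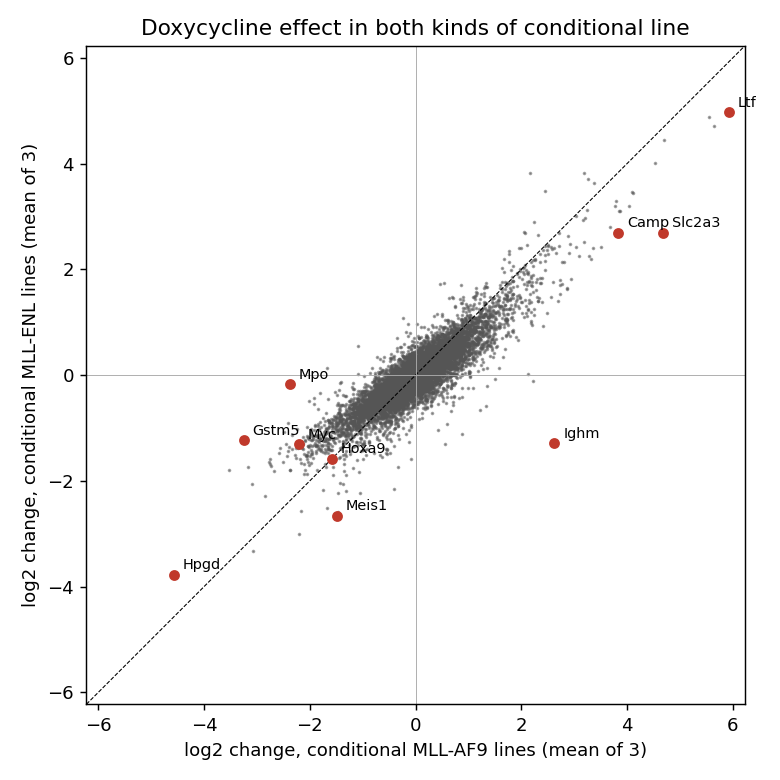
Log2 change with doxycycline in the conditional MLL-ENL lines (mean of 3) against that in the conditional MLL-AF9 lines (mean of 3), with 1 point per tested gene, 10 genes named in red and a dashed line of equality. Most points follow the dashed line, and Ighm lies apart, with a rise in the MLL-AF9 lines and a fall in the MLL-ENL lines.

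The difference between the oncogenes' effects passed for 7 genes, 4 of them with a higher and 3 with a lower change in the MLL-ENL lines. Gstm5, a glutathione transferase gene, had a mean change of -3.25 ± 0.34 in the MLL-AF9 lines and of -1.23 ± 0.30 in the MLL-ENL lines (SD, n = 3, adjusted p = 0.00957). The values were -1.67 ± 0.53 and 0.14 ± 0.08 for Hrob, a homologous recombination gene, -1.44 ± 0.20 and -0.15 ± 0.20 for the haem synthesis gene Uros, and for Chic2 -0.62 ± 0.04 and 0.27 ± 0.10. They were 2.63 ± 1.04 and -1.29 ± 0.46 for Ighm, the immunoglobulin mu heavy chain gene, 4.68 ± 0.35 and 2.69 ± 0.34 for Slc2a3, and for Tlr1 0.43 ± 0.31 and -1.04 ± 0.02. No preset gene passed: Mpo differed by 2.20 ± 0.70 (SE, adjusted p = 0.304) and Meis1 by -1.18 ± 0.33 (adjusted p = 0.28), although both passed without MA1 (adjusted p = 5.82e-06 and 0.0109). No other probe set of Chic2, Ighm or Slc2a3 passed for this difference. At an unadjusted p under 0.05 there were 1301 genes. The count rested on single lines: it was 1767 without MA1, 2 without MA4, 1 without ME4, 0 without ME5 and 1 without ME7. Camera called 17 lists for this difference, of which 0 passed with an estimated correlation and 0 with the directional test of fry, and 10 lists passed without MA3 and 11 without ME4. Of the 7 genes, Hrob, Uros, Chic2 and Ighm also differed between the untreated conditional lines. Their MLL-ENL minus MLL-AF9 values there were -1.499, -1.312, -0.74 and 6.057. For these genes the different changes started from different untreated levels. The same untreated arrays enter both comparisons, in the changes with a minus sign. Values of opposite sign are therefore partly built in, and the overlap is no separate finding. Slc2a3 had an untreated difference of 2.558 with its chosen probe set and 2.028 with its other one (adjusted p = 0.057 and 0.0209 among all probe sets).

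In the 2 constitutive lines no gene passed with limma (484 at an unadjusted p under 0.05, or 5.14%, and a smallest adjusted p of 0.11). The genes with the smallest p were P2rx3 at 1.52 ± 0.19 (SE of the fit, 2 lines), Pck2 at 1.34 ± 0.20 and the cysteine synthesis gene Cth at 3.49 ± 0.53, all higher, and Aldoc at -1.22 ± 0.25, Slc16a3 at -1.21 ± 0.27 and Bmt2 at -0.61 ± 0.14, and none of them passed. These SEs use a spread pooled over all lines. They understate how far the 2 constitutive lines lay apart for Cth and Pck2. Most of that spread comes from the conditional lines, where the SD of the log2 changes across genes was 0.575 to 0.976. It was 0.255 in cMA3 and 0.259 in cME3. For other genes the SEs may therefore be too wide, and the lack of calls does not show that doxycycline changed nothing. Single lines differed in size: in cMA3 and cME3 the changes were 4.80 and 2.18 for Cth, 1.82 and 0.85 for Pck2, and -0.74 and -1.67 for Slc16a3. The genes of the integrated stress response, induced through the factor ATF4, had a median of 0.52. None of the 29 passed over all genes, and 19 were higher adjusted over the list alone (camera adjusted p = 2.52e-26, adjusted p = 0.23 with an estimated correlation). Asns and Trib3 had changes of 1.03 ± 0.20 (1.401 in cMA3 and 0.654 in cME3) and 1.06 ± 0.21. The glycolysis and hypoxia list had a median of -0.27 (camera adjusted p = 1.01e-08, adjusted p = 0.479 with an estimated correlation), where 0 of 24 passed over all genes and 6 were lower and 1 higher adjusted over the list alone. The list of the HOXA cluster and its cofactors had a median of -0.15 in cMA3 and -0.46 in cME3 (camera adjusted p = 0.00729, adjusted p = 0.479 with an estimated correlation, and 0.409 without cME3), with 0 of 10 genes passing. Without cME3, 2 genes passed, Pck2 and Cth (adjusted p = 0.0316 for each), in a fit where the effect rests on cMA3 alone and its spread is taken from the conditional lines. Camera called 7 lists with both lines, 4 higher and 3 lower, and 2 without cME3, those of the stress response and of glycolysis and hypoxia. The others were oxidative phosphorylation, the mitochondrial ribosome and cytosolic ribosomal proteins, with medians of 0.14, 0.13 and 0.12, and G1/S and DNA replication, with a median of -0.11 (adjusted p = 0.812, 0.881, 0.812 and 0.919 with an estimated correlation). None of their genes passed, also adjusted over each list alone. With only the 4 arrays of these lines in the fit 133 genes passed, 87 higher and 46 lower. There the spread comes from these 2 lines alone.

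The change in the conditional lines beyond that in the constitutive lines passed for 3237 genes, 1548 higher and 1689 lower. Ifitm6 differed by 5.23 ± 0.58, Ltf by 5.02 ± 0.55, Ceacam10 by 4.99 ± 0.39, Cd177 by 4.68 ± 0.42, Itgb2l by 4.59 ± 0.28 and Olfm4, another neutrophil granule gene, by 3.98 ± 0.70. Of the 24 neutrophil genes 22 were higher (23 adjusted over the list alone, camera adjusted p = 4.18e-14, adjusted p = 0.404 with an estimated correlation). All 37 ribosome biogenesis genes were lower (camera adjusted p = 9.55e-16, adjusted p = 0.45 with an estimated correlation), as were Hpgd at -3.46 ± 0.36, Fkbp11 at -2.88 ± 0.48, Srm at -2.79 ± 0.46 and the nucleolar gene Gnl3 at -2.44 ± 0.41. Of 10 HOXA cluster and cofactor genes 6 were lower and 1 higher, with a median of -0.80 where that in the conditional lines alone was -1.19 (camera adjusted p = 0.0226, adjusted p = 0.404 with an estimated correlation, and 0.0507 without cMA3). Hoxa9 differed by -1.61 ± 0.19, Meis1 by -1.70 ± 0.33 (adjusted p = 0.065 without cMA3) and Hoxa5 by -0.75 ± 0.24, which did not pass without MA4, ME5, cMA3 or cME3, nor with its other probe set (adjusted p = 0.114 among all probe sets). The other reported fusion targets and the glycolysis and hypoxia genes did not pass as lists (camera adjusted p = 0.0696 and 0.781). Of the 29 stress response genes 19 were lower and 0 higher (22 lower adjusted over the list alone, camera adjusted p = 3.33e-07, adjusted p = 0.404 with an estimated correlation), and Cth had a difference of -3.08 ± 0.61 and passed. The count was 1149 without cMA3 and 482 without cME3, and each of these fits leaves 1 constitutive line, which is assumed to vary like the other lines. Olfm4 and Fkbp11 did not pass without cME3 (adjusted p = 0.0555 and 0.0522), nor Cth without cMA3 (adjusted p = 0.0653). Without the line as replicate block, 1940 genes passed.

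Untreated conditional lines were compared to ask how cells immortalised by MLL-ENL differ from those immortalised by MLL-AF9 while the oncogene is on. There were 22 genes that passed, 10 higher and 12 lower in the MLL-ENL lines. Ighm was higher by 6.06 ± 0.34 on the log2 scale (SE, 3 lines against 3, adjusted p = 0.000815), Lipg, encoding endothelial lipase, by 2.81 ± 0.35, Ccdc80 by 1.51 ± 0.17, Ppp1r14c by 1.497 ± 0.144 and Tmem273 by 1.40 ± 0.19. In the MLL-AF9 lines these genes lay near or below the level of the filter, 5.14 as log2(signal + 16). Their means there were 4.51, 5.21, 5.12, 4.80 and 4.64, so the sizes of these differences are uncertain. Mycn, a paralogue of Myc, was lower, with a difference of -2.53 ± 0.14 (adjusted p = 0.000815), as were Ssbp2 at -2.31 ± 0.20, Macir at -1.96 ± 0.24, Hrob at -1.499 ± 0.166 and the monocyte gene Cd14 at -1.37 ± 0.16. Hoxa9 was higher by 0.85 and passed. In untreated cMA3, which carries MLL-AF9 but was not part of the comparison, the level was nearer to the mean of the conditional MLL-ENL lines for 21 of the 22 genes, with Hoxa9 as the exception. In cME3 it was nearer to the MLL-ENL mean for 19. Of 9420 genes 1030 had an unadjusted p under 0.05. With the 2 constitutive lines added to their oncogenes 1 gene passed, and without MA3, MA4, ME4, ME5 or ME7 the count was 35, 3, 4, 4 or 3. Among the genes named here, Ighm and Mycn passed without each line in turn, and each of the others failed to pass without at least 1 line. Of the other probe sets 1 of 2 for Ighm and 1 of 1 for Macir did not pass. Camera called 8 lists, of which 0 passed with an estimated correlation, and without MA4 it called 5.

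**Figure D4:**
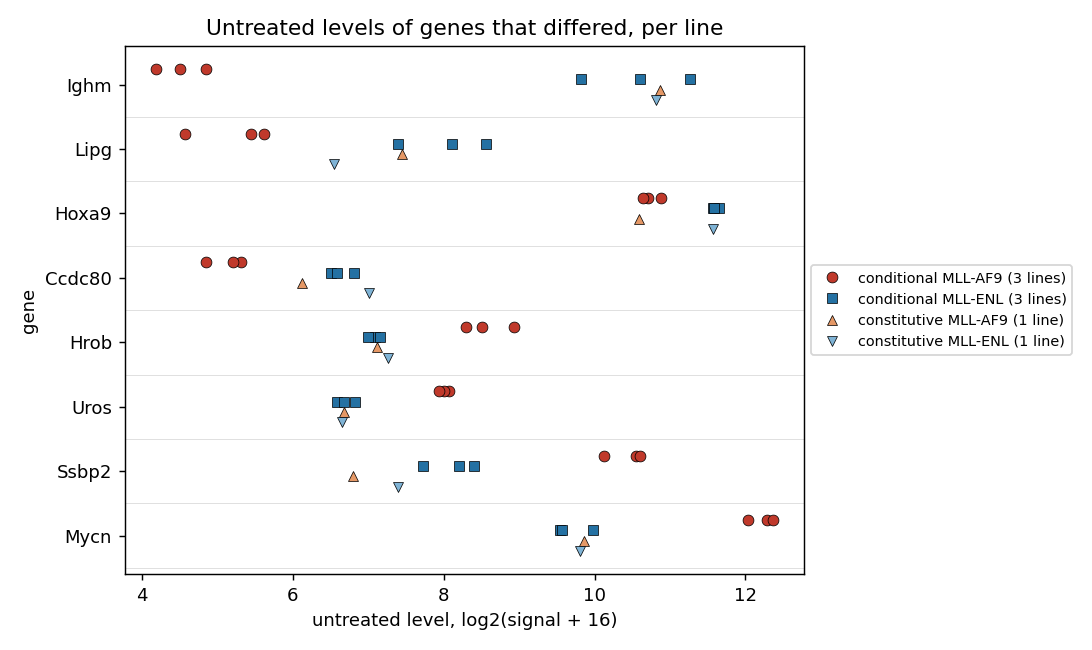
Untreated level of 8 of the genes that differed, as log2(signal + 16), in each of the 8 lines. For Mycn and Ighm the constitutive MLL-AF9 line, at 9.86 and 10.87, lies with the MLL-ENL lines and apart from the conditional MLL-AF9 lines, whose means are 12.23 and 4.51.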

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

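The tests in this part were chosen or worded after the results they measure had been seen, except those of the array scaling and of the genes around Mycn.

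The rise of neutrophil genes in the conditional lines was weighed first, since the difference from the constitutive lines passed for 3237 genes. An effect of doxycycline itself is argued against by the median of the list in the conditional minus constitutive comparison, 2.48, and by constitutive medians of 0.16 and 0.00, below the lowest conditional median of 1.88. The median was 2.28 after quantile normalization, compared with 2.37 as given, so unequal scale of the arrays does not account for the rise. The trimmed means already lay between 174.8 and 178, so this test could hardly have come out otherwise. Both scalings make the arrays alike in total signal, and neither can show a change in total RNA per cell. The gap to the monocyte list was 1.74 ± 0.47 (SD, n = 6 lines) and above 0 in 6 of 6 lines (2.10 ± 0.35 to the mast cell list). It shows that the markers of other cell types did not rise by equal amounts. It cannot decide about a lower share of progenitors, since a list's change also depends on how much progenitors express its genes. Maturation of the cells toward neutrophils and overgrowth of a neutrophil fraction already present could both give the rise of neutrophil genes, and the arrays do not separate them.

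Other splits of the lines were refitted. Exchanging treated and untreated arrays within lines gave as many genes in 1 of 32 arrangements, the real one with 6026. The highest other gave 7. Choosing other pairs of lines as constitutive gave as many in 1 of 28 choices. The real one had 2843 under a common conditional effect and the highest other 911. These shares are under 0.05 and the smallest that 32 and 28 splits can give. They argue against chance but do not exclude it. Exchanging a line with a large change also widens the spread of the fit, which lowers the other counts. For each oncogene there are only 4 arrangements, too few for a share under 0.05: 5258 against a highest other of 0 for MLL-AF9, and 4106 against 0 for MLL-ENL, each reached by 1 arrangement. The 10 splits of the 6 conditional lines are also too few for such a share. For the difference of the effects the real count was 7 and the highest other 9, with 2 splits as large. There a split that does not follow the oncogenes gave more genes than the real one. For the untreated lines the real count was 22 and the highest other 1.

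The higher stress response genes in the constitutive lines were weighed as the second pattern. Doxycycline acting alike in every line, with nothing to offset it, is argued against by a median of -0.84 in the conditional minus constitutive comparison. The median was 0.49 after quantile normalization, compared with 0.52 as given, so unequal scale of the arrays does not account for it. The limits given above for the neutrophil list hold here too. An effect of doxycycline that the loss of the oncogene hides in the conditional lines may remain, as may a difference in the cultures of these 2 lines, and neither was tested. Because no gene passed by itself and the call was lost with an estimated correlation, the pattern is a hypothesis.

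The untreated difference between the oncogenes was weighed as the third. A gain in the MLL-AF9 lines that spans the 6 nearest tested genes around Mycn is argued against by their median difference of -0.069 (range -0.395 to 0.194, none passing), but a smaller gain stays open, since Ddx1 and Nbas on one side were at -0.179 and -0.395. Whether the oncogene itself sets these genes cannot be told apart from a property shared by MA1, MA3 and MA4, such as a common origin, which was not tested, because untreated cMA3 was nearer to the conditional MLL-AF9 mean for 1 of the 22 genes and is a single line with another construct. B cells in the MLL-ENL cultures as the source of Ighm stay open: the highest other B cell gene, Igll1, had a median signal of 14.1 in these lines, but no other B cell gene exceeded 66.6 on any array, and a low signal from probe sets near the floor decides nothing.

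The difference of the doxycycline effect between oncogenes passed for 7 genes, with MLL-ENL minus MLL-AF9 values of 2.02 for Gstm5, 1.81 for Hrob, 1.28 for Uros, 0.89 for Chic2, -3.91 for Ighm, -1.99 for Slc2a3 and -1.48 for Tlr1. Since another split of the conditional lines gave 9 genes, a count of 7 is no more than differences between lines can give. Among the 6 conditional lines 73 quantities were examined for a line far from the others, and 1 stood out, where chance gives about 1 in 20: the median change of the other reported fusion targets was -0.21 in MA3 and between -0.59 and -0.45 elsewhere. Of 2482 tested probe sets without a gene name, 1386 passed in the conditional lines and 0 in the constitutive lines.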

How the results depend on the processing

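The fit without both MA3 and MA4 was chosen after the data were seen, and the other alternatives were planned. Signal near background limits what can be seen of weakly expressed genes. Of the counts of genes under settings other than leaving out a line, 78 stayed within 1.5 times and 23 did not, and of the values of single genes 2656 kept their direction and side of the threshold, 77 lost a call, 14 gained one and 6 turned direction. Of the values of single lists 135 kept their side of the threshold and 141 lost a call. Where no cause is named, the cause was not tested.

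Counted as probe sets, of which there are more than genes, 11438 passed in the conditional lines, 9865 for MLL-AF9, 7191 for MLL-ENL, 3 for their difference, 5571 for conditional minus constitutive and 35 between untreated lines, and 5966 were shared by both oncogenes. A minimum of 2-fold, a stricter rule, left 1028, 1400, 790, 1127 and 14 genes for the conditional, MLL-AF9, MLL-ENL, conditional minus constitutive and untreated comparisons.

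Without the line as replicate block 3 genes passed for the difference between oncogenes and 1940 for conditional minus constitutive (1935 of the 3237), and 5307 in the conditional lines. With the repeat number as replicate block for the untreated lines 27 passed. The difference between oncogenes gave 4 genes without an intensity trend, 2 with the mean of the probe sets and 3 with only the arrays compared. In the constitutive lines 1 gene passed with a pseudocount of 64, 3 without a filter and 133 with only their arrays, where the spread comes from 2 lines. Between untreated lines 7 passed with a floor of 32, 1 with the constitutive lines included and 1 in the treated arrays.

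With an estimated correlation 0 lists passed in each of the 7 comparisons. The directional test of fry called 12 lists higher and 8 lower in the conditional lines, and 11 and 8 for MLL-AF9. It called 6 and 5 for MLL-ENL, and 4 and 6 for conditional minus constitutive. It gave 0 for the difference between oncogenes, the constitutive lines and the untreated lines. Its mixed test gave 26 in the conditional lines, 25 for MLL-ENL, 1 for the difference, 0 in the constitutive lines, 25 for conditional minus constitutive and 2 between untreated lines.

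Leaving out each line in turn, the count was 2424 to 2951 for MLL-ENL, 0 to 1767 for the difference between oncogenes, 0 to 2 in the constitutive lines, 482 to 4460 for conditional minus constitutive and 3 to 35 between untreated lines. The numbers of lists were 10 to 19 for the difference, 2 to 9 in the constitutive lines and 5 to 9 between untreated lines.

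Without both MA3 and MA4, MA1 was the only MLL-AF9 line left. The conditional effect then gave MA1 the same weight as the mean of the 3 MLL-ENL lines, so the values of this fit lean on MA1. Of genes that did not pass in all 6 lines, Jmjd1c turned to -0.07, Elane to 0.124, Csf1r to -0.004, Cd14 to -0.263 and Irf8 to 0.06. Over the lines left out in turn Cd14 ranged from -0.009 (without ME5) to 0.438, and Irf8 from -0.152 to 0.015 (without ME4). Hrob was at 0.311 in the treated arrays against -1.499 in untreated ones, and did not pass there.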

Other observations

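The tests of gene lists in this part were planned, and the values of Aldh1a7 were looked up after its spread had been seen. Some changes in the conditional lines lay outside the groups described so far. Of all tested genes 64% passed in these lines, so a count of calls in a list says little by itself. Of 17 apoptosis regulators 10 rose and 1 fell (camera adjusted p = 0.0471, adjusted p = 0.586 with an estimated correlation), with Casp6 at 0.95, the pro-apoptotic gene Bcl2l11 at 0.68 and Bid at -0.55. Of 18 p53 target genes 6 rose and 3 fell (camera adjusted p = 0.436), with Trp53inp1 at 2.47, Btg2 at 1.58, Apaf1 at 0.80 and Mdm2 at 0.70. Of 19 cholesterol synthesis genes 9 fell and 2 rose (camera adjusted p = 0.0473, adjusted p = 0.586 with an estimated correlation), among them Scd1 at -1.90 and Dhcr7 at -1.17. Of 28 lysosome and phagosome genes 15 rose and 3 fell (camera adjusted p = 0.0375, adjusted p = 0.61 with an estimated correlation), and of 15 integrin and adhesion genes 8 rose and 1 fell (camera adjusted p = 0.0382, adjusted p = 0.586 with an estimated correlation), among them Alcam at 2.04 and Itgal at 1.45. Of 27 chromatin partners of the fusions 7 fell, including Bmi1 at -0.69 and Ash2l at -0.61, and 4 rose, with a median of 0.01 as given and -0.04 after quantile normalization (camera adjusted p = 0.697). Calls of these lists were lost without single lines: cholesterol synthesis and apoptosis without MA3 (adjusted p = 0.0691 and 0.0699), MA4, ME5 or ME7, apoptosis also without ME4 (adjusted p = 0.051), and lysosome and integrins without MA3 (adjusted p = 0.0699 for each) or ME5 (adjusted p = 0.075 and 0.0724).

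For the conditional minus constitutive difference the cholesterol synthesis and lysosome lists did not pass (camera adjusted p = 0.171 and 0.0614). Of 29 integrated stress response genes 13 fell and 4 rose in the conditional lines (camera adjusted p = 0.0972), and of 11 reference genes 5 fell and 3 rose (camera adjusted p = 0.707). Lists with fewer than 5 tested genes were counted only: dendritic cell and MHC class II genes had 1 rise and 1 fall among 3, eosinophil genes 1 rise among 1, erythroid genes 1 rise and 1 fall among 4, megakaryocyte genes 2 rises among 3, T and NK cell genes no call with limma among 2, stromal genes 1 fall among 2 and sex-linked genes no call among 1. No B cell list gene was above the filter.

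Aldh1a7 was uneven between lines before treatment. Its untreated signal was high in MA1, MA4 and ME4 and low in the other conditional lines, and its change with doxycycline had an SD of 2.34 over the 6 lines, the widest of the genes named for the conditional lines.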
